A study of Mus musculus with 6 samples.

How the data were processed

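Bulk RNA-seq was measured in 6 libraries of stromal cells sorted from injured mouse quadriceps as negative for CD45 and CD31 and positive for CD29, and separated by a tdTomato reporter of p16 expression on the C57Bl/6 background. Per the labels, 3 libraries came from reporter-positive (p16+) and 3 from reporter-negative (p16-) cells. The labels' protocols describe removal of quadriceps muscle at 10 weeks of age, filling of the defect with 30 mg of polycaprolactone particles, a decellularized matrix or 50 uL of saline, and harvest after 1 or 6 weeks. Which filler and which harvest time these libraries had is not given in the sources used here. It is therefore not known whether both were the same for p16+ and p16- libraries. Per the labels' protocols, RNA was taken up in TRIzol and purified on columns, libraries were made with a kit that does not mark strand, samples with an RNA integrity number under 7 were left out, and sequencing was paired-end with 50 bp per end at a target of 30M reads.

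The deposited values were whole-number counts of fragments per gene, made by the authors with featureCounts 1.6.0 on the exons of GENCODE release vM21, per the file headers. Read pairs were counted as single fragments and no option for strand, overlapping genes or multiply mapped reads stood in the command, so that fragments shared by overlapping genes were not counted under the program's defaults. Reads were demultiplexed with bcl2fastq and aligned with STAR 2.7.3a to GRCm38.p6, per the submitters' processing notes. All 55536 gene identifiers and their start and end positions matched the vM21 annotation, from which symbols were taken. Gene-level counts cannot separate the 2 proteins of Cdkn2a, p16Ink4a and p19Arf. Without strand, fragments in the overlap of genes on opposite strands are lost or go to either gene, and overlap is given beside the named genes where it exceeded 10% of the exonic length.

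The computations started from these counts. Total counts lay between 35253406 and 39103909 per library, and a count of 3 in a library corresponded to 0.0767 to 0.0851 CPM, the unit of counts scaled to the size of the library. Genes were filtered with filterByExpr at its defaults, which left 15903 genes that held 99.918% to 99.932% of the counts. Normalization factors (TMM), the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) and CPM were from edgeR 4.0.16 in R 4.3.3. All adjusted p-values of genes are from this edgeR test with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05, unless another test is named. Fold changes are p16+ over p16-, the model held the group alone, and the common biological coefficient of variation was 0.158. Log2 CPM used a prior count of 2. CPM values are means ± SD over 3 libraries per group.

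Before the data were examined, 31 gene lists were fixed from general knowledge: cyclin-dependent kinase inhibitors, p53 targets, cytokines and proteases of the senescence-associated secretory phenotype, proliferation, fibrillar matrix, basement membrane, cartilage, tendon, bone, myofibroblast, TGF-beta response, Wnt, fibro-adipogenic progenitor, interferon response, complement, lysosome, hypoxia and glycolysis, immediate-early response, and markers of macrophages and other leukocytes, MHC class II, neutrophils, lymphocytes, endothelium, pericytes and smooth muscle, satellite cells, muscle fibres, glia, adipocytes, erythroid cells and epithelium. The 30 lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with adjustment over the lists. Named genes followed a rule fixed at the same time: Cdkn2a and the genes of the sort gate; the 12 genes with the largest rise and the 12 with the largest fall that passed the threshold, had a mean log2 CPM of at least 2, did not overlap between groups and were not gene models without a name; up to 4 members with the smallest p in each list, or its most abundant member where none passed; and genes that a test in the closing section needed. The values of some members of the lists are not reported here. The last group is Il6, Cxcl1, Cxcl2, Ccl2 and Ccl7, chosen after their values were seen. Genes named outside the rule, also after their values were seen, are Col3a1, Mki67, Pdgfra, Sfrp1, Sfrp2, Sfrp4, Wif1, Frzb and further genes in the closing section.

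The gene test was tested on counts simulated for this comparison, with 200 genes changed by known folds among the 15499 genes that passed the filter. It recovered 62% of the genes changed 1.5-fold, 78% at 2-fold, 87.2% at 3-fold and 93.8% at 4-fold, and 13 of its 169 calls were false. On data simulated over 15903 genes, the list test called a list of 20 genes raised 1.5-fold and 0 of 100 unchanged lists. That simulation drew genes independently and says nothing of lists whose genes vary together.

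The alternatives fixed beforehand were RLE and upper-quartile factors, no filter and a stricter filter (CPM of at least 1 in 3 libraries), non-robust estimation, removal of mitochondrially encoded genes, the replicate number as a block, removal of each library in turn, the DESeq2 1.42.0 Wald test, limma-voom, camera with an estimated correlation and fry. Library sizes alone and removal of the 20 most abundant genes were added after seeing the data. Libraries were compared for duplication by a chi-square statistic over genes with a mean count of at least 10; it was at least 11.9 per degree of freedom in each pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.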

Results

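Stromal cells of injured mouse quadriceps were sorted by a fluorescent reporter of p16, the cell cycle inhibitor encoded by Cdkn2a whose expression is widely used as a mark of senescent cells, and profiled by RNA-seq. There were 3 libraries of reporter-positive (p16+) and 3 of reporter-negative (p16-) cells. Totals were 35253406 to 37861713 counts in p16+ and 36507067 to 39103909 in p16-. Mitochondrially encoded genes took 1.11% to 1.26% of the counts in p16+ and 1.22% to 1.37% in p16-. The 20 most abundant genes of a library took 25.65% to 26.33% in p16+ and 20.32% to 22.11% in p16-, led in each library by the collagen gene Col3a1. On principal components of log2 CPM the first, with 41.2% of the variance, placed the 3 p16+ libraries on the opposite side from the 3 p16- libraries. The second, with 18.1%, set p16+ replicates 2 and 3 far apart, at 38.22 and -46.65. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

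Cdkn2a itself (ENSMUSG00000044303.6, chromosome 4, 89274471 to 89294653, minus strand, GRCm38) stood at 7.82 ± 0.961 CPM in p16+ and 2.13 ± 0.329 CPM in p16- (SD, n = 3 each). This was a log2 fold change of 1.88 (SE 0.22, adjusted p = 2.0e-05 by edgeR's quasi-likelihood test), or 3.67-fold. The counts were 251, 324 and 265 in p16+ and 98, 70 and 82 in p16-, so the transcript was also measured in the reporter-negative cells. The exact two-sided permutation test on log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the genes of the sort gate, Itgb1, which encodes CD29, was abundant in both groups, at 891 ± 21.7 and 758 ± 53.4 CPM (adjusted p = 0.0543). Ptprc, which encodes CD45, had 7.77 ± 2.22 CPM in p16+ and 4.89 ± 0.929 in p16- (adjusted p = 0.0602). Pecam1, which encodes CD31, was higher in p16+ at 6.73 ± 1.58 against 3.34 ± 0.778 CPM (adjusted p = 0.00871). The calls of these 3 gate genes depended on the setting. Without p16+ replicate 3 the adjusted p of Pecam1 was 0.0621 and that of Ptprc 0.0172. Without p16- replicate 2 those of Ptprc and Itgb1 were 0.0371 and 0.0469.

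**Figure D1:**
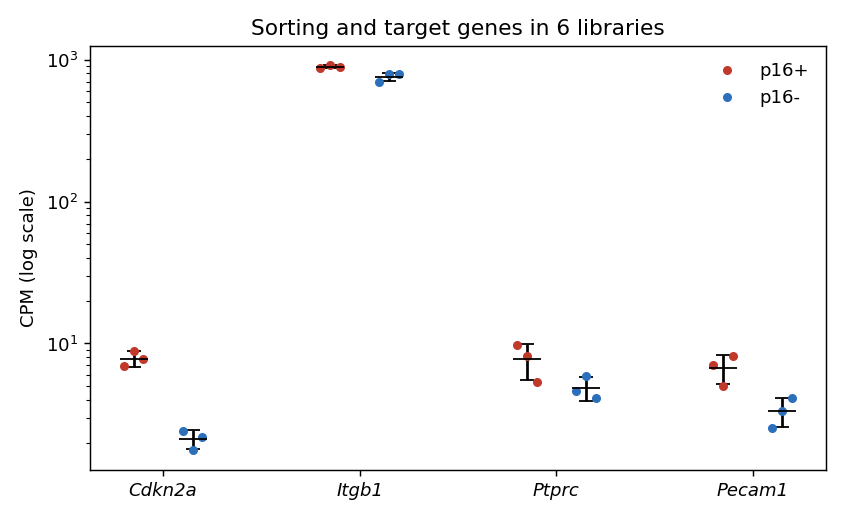
CPM on a log axis of Cdkn2a and the 3 sort gate genes in the 3 p16+ (red) and 3 p16- (blue) libraries; each point is a library, and black bars give the mean and SD. Cdkn2a had a mean of 7.82 CPM in p16+ and 2.13 CPM in p16-, while Itgb1 stood at 891 and 758 CPM.

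The comparison of p16+ with p16- cells asks how the transcriptome of reporter-positive stromal cells differs from that of reporter-negative ones. By camera at its preset correlation, the lists of fibrillar matrix genes, of proteases with their inhibitors and growth factor binding proteins, of p53 targets and of lysosomal genes were higher in p16+ cells, and those of progenitor markers, interferon response genes and glial genes were lower. With an estimated correlation 0 of the 30 tested lists passed, and the smallest adjusted p was 0.102. Of 15903 genes tested, 2660 (16.73%) passed the threshold, 1382 higher and 1278 lower in p16+. A change of at least 2-fold was seen in 669 of them, 301 higher and 368 lower. Among the changed genes, 2613 had no overlap of values between the groups, as did 5260 of all genes tested, where chance gives 10%. With library sizes alone, a scaling chosen after seeing the data, 36.0% of the changed genes were higher in p16+ in place of 52.0%.

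The largest rises were in genes of several functions. Kif26b (chromosome 1, 178529125 to 178939200), a kinesin family member, rose from 9.39 ± 3.78 to 45.4 ± 7.39 CPM (log2 fold change 2.27, SE 0.24, adjusted p = 0.000144). The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283331) rose from 30.3 ± 7.36 to 139 ± 33.7 CPM (2.20, SE 0.23, adjusted p = 0.00052). Ddah1 (chromosome 3, 145758675 to 145894277), whose enzyme degrades asymmetric dimethylarginine, rose from 10.3 ± 2.17 to 45.1 ± 6.24 CPM (2.14, SE 0.15, adjusted p = 1.59e-07). Ltc4s, Cryaa, Prss35, Reg1, Mmp10, Brinp3, Megf6, Cdkn2a and Cldn1 completed the group of 12, with log2 fold changes from 1.87 for Cldn1 to 2.27 for Ltc4s. Of the exonic length of Ltc4s 26.4% is overlapped by Gm26542, and of Cryaa 13.2% by another gene, each on the opposite strand, which unstranded counts cannot tell apart.

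The largest fall was in Smpd3 (chromosome 8, 106252548 to 106337988), which encodes neutral sphingomyelinase 2, from 96.0 ± 15.1 CPM in p16- to 13.1 ± 4.94 CPM in p16+ (log2 fold change -2.88, SE 0.26, adjusted p = 0.000215). Col20a1 (chromosome 2, 180986535 to 181018363), a collagen gene, had 50.0 ± 11.8 CPM in p16- and 9.15 ± 1.92 in p16+ (-2.45, SE 0.17, adjusted p = 1.77e-07). The chemokine gene Cxcl13 had 37.4 ± 7.08 and 7.39 ± 2.79 CPM (-2.34, adjusted p = 2.64e-05), and the decoy receptor gene of interleukin 1, Il1r2, 43.8 ± 10.0 and 10.2 ± 3.77 CPM (-2.10, adjusted p = 0.00149). L1cam and Nrcam, which encode neural cell adhesion molecules, and Kcna2, a potassium channel gene, fell by 2.36, 2.32 and 2.18 on the log2 scale. Ppp2r2b, Car8, Krt19, Bche and Dmrt2 were the other members of this group, with log2 fold changes from -2.44 to -2.18.

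Cell cycle inhibitors and p53 targets were higher in p16+ cells. Of 7 cyclin-dependent kinase inhibitor genes, 4 rose, 0 fell and 3 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.00122, adjusted p = 0.102 with an estimated correlation). Cdkn2a is a member of this list and was the basis of the sort, and the list was not tested without it. Its neighbour Cdkn2b rose from 7.79 ± 1.94 to 18.0 ± 2.57 CPM (adjusted p = 0.00016) and Cdkn1a, the p21 gene, from 138 ± 5.49 to 189.8 ± 2.07 CPM (adjusted p = 0.000277). Of 19 p53 target genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000109, adjusted p = 0.102 with an estimated correlation). Without p16+ replicate 2 or p16+ replicate 3 the number that fell was 1, and with library sizes alone 9 rose and 3 fell. Phlda3, a repressor of Akt signalling, rose from 33.9 ± 3.69 to 71.9 ± 5.9 CPM, and the death receptor gene Eda2r from 19.6 ± 4.21 to 37.2 ± 5.51 CPM. Of 39 proliferation genes, 5 rose, 0 fell and 34 did not pass (5 and 0 adjusted over the list alone; camera adjusted p = 0.00169, adjusted p = 0.251 with an estimated correlation). With library sizes alone 4 rose and 1 fell. Top2a, a DNA topoisomerase gene of dividing cells, rose from 3.81 ± 1.55 to 10.0 ± 1.26 CPM, and Cdk1, the mitotic kinase gene, from 2.18 ± 1.2 to 6.22 ± 1.25 CPM. Mki67, another marker of dividing cells, named outside the fixed rule after its value was seen, had 9.99 CPM in p16+ and 7.60 in p16- (adjusted p = 0.299).

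The secreted factors associated with senescence went in both directions. Of 22 protease, inhibitor and binding protein genes, 14 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 3.03e-07, adjusted p = 0.102 with an estimated correlation). Mmp3, which encodes stromelysin 1, rose from 781 ± 102 to 1897 ± 216 CPM and the metalloproteinase inhibitor gene Timp1 from 204 ± 26.3 to 541 ± 37.8 CPM, while Plau, the urokinase gene, fell from 561 ± 39.7 to 307 ± 26.8 CPM (adjusted p = 3.88e-06). Of 27 cytokine and growth factor genes, 6 rose, 9 fell and 12 did not pass (7 and 9 adjusted over the list alone). The list did not pass camera (adjusted p = 0.321) and passed fry for change in either direction (adjusted p = 0.000314). The inflammatory cytokine gene Il6 fell from 693 ± 155 to 407 ± 27.7 CPM (adjusted p = 0.000292) and the neutrophil chemokine gene Cxcl1 from 1343 ± 267 to 809 ± 25.9 CPM (adjusted p = 0.00021). The angiogenic factor genes Vegfa and Fgf2 fell by 1.00 and 1.26 on the log2 scale, and 13.2% of the exonic length of Fgf2 is overlapped by other genes. Tnfrsf11b, which encodes osteoprotegerin, rose from 11.9 ± 2.68 to 28.9 ± 2.89 CPM. Of 18 immediate-early genes, which respond to stimulation and handling, 1 rose, 7 fell and 10 did not pass (2 and 9 adjusted over the list alone; camera adjusted p = 0.00924, adjusted p = 0.538 with an estimated correlation). By fry for a common direction the list did not pass (adjusted p = 0.0968). The number that rose was 3 without p16- replicate 1 and 0 without p16+ replicate 2, p16+ replicate 3 or p16- replicate 3 and with library sizes alone, where 10 fell. Atf3 fell from 1980 ± 272 to 1172 ± 114 CPM and Egr1 from 4925 ± 317 to 3668 ± 113 CPM.

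Of 24 fibrillar matrix genes, 18 rose, 0 fell and 6 did not pass (18 and 0 adjusted over the list alone; camera adjusted p = 1.41e-17, adjusted p = 0.178 with an estimated correlation), with a median log2 fold change of 0.59. Without p16- replicate 1, 1 member was called lower. Col1a1 (chromosome 11, 94936224 to 94953042) rose from 20414 ± 2008 to 37831 ± 909 CPM (log2 fold change 0.89, SE 0.09, adjusted p = 2.66e-06), the matricellular gene Tnc from 236 ± 50.3 to 663 ± 59.5 CPM, and Lox, whose enzyme crosslinks collagen, from 382 ± 56.3 to 839 ± 113 CPM. Of 16 basement membrane genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.187). The number that rose was 3 without p16+ replicate 2, p16+ replicate 3 or p16- replicate 1, and the number that fell was 2 without p16+ replicate 2 or p16- replicate 3. With library sizes alone 3 rose and 4 fell. The list passed without the filter on low counts (adjusted p = 0.0493). Col18a1 rose from 564 ± 82.9 to 1222 ± 67.5 CPM and Nid1, the nidogen 1 gene, fell from 2588 ± 319 to 1769 ± 8.98 CPM.

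Of 19 cartilage genes, 7 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 9.38e-05, adjusted p = 0.272 with an estimated correlation). The number that rose was 4 without p16+ replicate 3 or p16- replicate 3. The number that fell was 2 without p16+ replicate 1 and 0 without p16+ replicate 2, p16+ replicate 3, p16- replicate 1 or p16- replicate 3. The minor fibrillar collagen gene Col11a1 rose from 20.4 ± 1.33 to 52.4 ± 12.5 CPM, and Cilp, a cartilage matrix gene, from 872 ± 109.9 to 1381 ± 45.4 CPM. Of 10 tendon genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.000135, adjusted p = 0.272 with an estimated correlation), among them Thbs4 from 1414 ± 87.6 to 2637 ± 327 CPM. By fry for a common direction the tendon list did not pass (adjusted p = 0.0521). Of 8 bone genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.000127, adjusted p = 0.102 with an estimated correlation). The other 4 bone genes did not pass. With any 1 library left out, or with library sizes alone, 3 rose and Dmp1 lost its call. Of these 3, Runx2 is also in the cartilage list and Col1a1 in the fibrillar matrix list. Runx2, the osteoblast transcription factor gene, rose from 22.7 ± 2.85 to 43.7 ± 5.3 CPM. The osteopontin gene Spp1 rose from 118 ± 27.3 to 376 ± 46.5 CPM, with 18.8% of its exonic length overlapped by another gene.

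Of 13 myofibroblast genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 6.37e-06, adjusted p = 0.102 with an estimated correlation). Cthrc1, a secreted collagen triple helix protein gene, rose from 73.0 ± 14.6 to 170.4 ± 15.7 CPM, and the collagen receptor gene Itga11 fell from 229 ± 19.7 to 135 ± 7.67 CPM. Of 10 pericyte and smooth muscle genes, 6 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00229, adjusted p = 0.272 with an estimated correlation), among them Notch3 from 195 ± 22.0 to 334 ± 14.0 CPM. In this list 1 member was called lower without p16+ replicate 1, without p16- replicate 2 or with library sizes alone. Of 16 TGF-beta response genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.00805, adjusted p = 0.196 with an estimated correlation). Pmepa1 rose from 154 ± 11.2 to 265 ± 21.4 CPM, and Ltbp1, which encodes a protein that binds latent TGF-beta, fell from 326 ± 23.0 to 152 ± 24.0 CPM. Of 17 Wnt pathway genes, 8 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.000492, adjusted p = 0.102 with an estimated correlation). This list holds ligands, response genes and secreted inhibitors, such as the Sfrp genes, Wif1 and Frzb, together. Its call therefore gives no direction of Wnt signalling. Ccn4, a Wnt-induced secreted protein gene, rose from 23.4 ± 4.04 to 73.3 ± 9.56 CPM, and the ligand gene Wnt11 fell from 47.4 ± 0.573 to 21.9 ± 3.7 CPM. The Dickkopf family gene Dkk3 rose from 103 ± 10.6 to 232 ± 16.7 CPM and its relative Dkk2 fell from 84.0 ± 12.7 to 35.2 ± 5.07 CPM. Named outside the fixed rule after their values were seen, Sfrp2 rose from 377 to 817 CPM (16.1% of its exonic length is overlapped by other genes), Sfrp1 from 167 to 288 CPM, Wif1 from 5.88 to 15.9 CPM and Frzb from 1.62 to 3.71 CPM, and Sfrp4 did not pass at 961 and 1082 CPM (adjusted p = 0.17). The call of Frzb was lost without p16+ replicate 2, p16+ replicate 3 or p16- replicate 2 (adjusted p = 0.0512, 0.0645 and 0.0509).

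Markers of fibro-adipogenic progenitors, the resident mesenchymal cells of muscle, were lower. Of 16, 0 rose, 11 fell and 5 did not pass (0 and 12 adjusted over the list alone; camera adjusted p = 3.49e-19, adjusted p = 0.102 with an estimated correlation). Dpp4 (chromosome 2, 62330073 to 62412231), a marker of early fibroblast progenitors, fell from 312 ± 11.4 to 101 ± 16 CPM (log2 fold change -1.62, SE 0.10, adjusted p = 6.86e-08), and the gelsolin gene Gsn from 24621 ± 2994 to 9381 ± 1561 CPM. Pdgfra, a general marker of these cells, named outside the fixed rule after its value was seen, had 866 CPM in p16+ and 1018 in p16- (adjusted p = 0.102), and was called lower without p16- replicate 1 (adjusted p = 0.00378), without the filter on low counts (adjusted p = 0.0411) and with library sizes alone (adjusted p = 0.0248). Of 22 interferon response genes, 0 rose and 10 fell (0 and 11 adjusted over the list alone; camera adjusted p = 2.17e-05, adjusted p = 0.272 with an estimated correlation). Without p16+ replicate 1, 1 member was called higher. Ifit1 fell from 69.8 ± 15.7 to 31.4 ± 3.16 CPM and the chemokine gene Cxcl9 from 107 ± 24.6 to 46.7 ± 4.92 CPM.

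Lysosomal genes and leukocyte markers were higher in p16+ libraries. Of 20 lysosomal genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 3.75e-05, adjusted p = 0.178 with an estimated correlation). Ctsk, which encodes the collagen-degrading cathepsin K, rose from 738 ± 59.0 to 1269 ± 51.7 CPM. Of 15 macrophage and other leukocyte markers, which the gate against CD45 would remove, 8 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.75e-05, adjusted p = 0.236 with an estimated correlation). The macrophage receptor gene Csf1r rose from 12.5 ± 3.28 to 28.2 ± 3.39 CPM, with 15.1% of its exonic length overlapped on the opposite strand, and the lysozyme gene Lyz2 from 124 ± 12 to 168 ± 8.41 CPM. Of 7 MHC class II genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0442, adjusted p = 0.378 with an estimated correlation). The list no longer passed without p16+ replicate 1 (adjusted p = 0.12) or p16- replicate 2 (adjusted p = 0.137), and the number that rose was 1 without p16+ replicate 1 or p16+ replicate 3. Of 13 complement genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.548), and 1 fell without p16+ replicate 1 or p16+ replicate 2. With library sizes alone 2 of them rose and 2 fell. Of 15 hypoxia and glycolysis genes, 3 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.417), and with library sizes alone 2 rose and 3 fell.

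Markers of other cells of muscle moved in different directions. Of 10 glial genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone; camera adjusted p = 1.1e-13, adjusted p = 0.115 with an estimated correlation), with a median log2 fold change of -1.82. The Schwann cell receptor gene Erbb3 fell from 11 ± 1.32 to 2.94 ± 0.69 CPM and the cadherin gene Cdh19 from 14.7 ± 4.87 to 3.56 ± 0.242 CPM. Of 12 endothelial genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.143). Without p16+ replicate 3 the number that rose was 3, and the list passed without p16+ replicate 2 (adjusted p = 0.0289) and without the filter on low counts (adjusted p = 0.047). The vascular receptor gene Flt1 rose from 6.00 ± 1.91 to 13.0 ± 2.77 CPM, whereas the angiopoietin receptor gene Tek fell from 168 ± 13.8 to 49.2 ± 7.79 CPM (adjusted p = 5.24e-08). Of 9 satellite cell genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0448, adjusted p = 0.247 with an estimated correlation). Leaving out any library except p16- replicate 2 ended the call of this list, with 1 gene higher and an adjusted p of 0.186 without p16+ replicate 1 and an adjusted p of 0.263 without p16- replicate 1, 0.0593 without p16- replicate 3, and 0.0748 and 0.0829 without p16+ replicates 2 and 3. With the stricter filter its adjusted p was 0.0633. The adhesion molecule gene Vcam1 rose from 123 ± 11.5 to 209.9 ± 21.5 CPM, and Myog, the gene of the differentiation factor myogenin, fell from 2.82 ± 1.69 to 0.422 ± 0.133 CPM.

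Few other markers passed. Of 14 muscle fibre genes, 0 passed (0 adjusted over the list alone; camera adjusted p = 0.773), and the actin gene Acta1 had 8.76 ± 3.81 and 7.53 ± 1.83 CPM. Of 4 neutrophil genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.417), the collagenase gene Mmp8, from 0.560 ± 0.345 to 2.54 ± 0.903 CPM, a call lost without p16+ replicate 2 (adjusted p = 0.0524). Of 3 lymphocyte genes, 0 passed (1 rose adjusted over the list alone; camera adjusted p = 0.417), with the T cell receptor gene Trac at 0.626 ± 0.185 and 0.804 ± 0.188 CPM. Of 3 adipocyte genes 0 passed (1 fell adjusted over the list alone; camera adjusted p = 0.309), and the fatty acid binding protein gene Fabp4 had 28.8 ± 8.99 and 29.4 ± 16.4 CPM. Of the adipocyte genes, 1 was called lower without p16+ replicate 1 and 2 without p16- replicate 2. Of 5 erythroid genes, 1 fell (2 adjusted over the list alone; camera adjusted p = 0.105). Without p16- replicate 2 the number that fell was 3 and the list passed (adjusted p = 0.00762), as it did without p16+ replicate 3 (adjusted p = 0.0355) and without the filter on low counts (adjusted p = 0.0362). Without p16+ replicate 1, p16+ replicate 2, p16- replicate 1 or p16- replicate 3 the number that fell was 0. The gene that fell was Alas2, the haem synthesis gene of red cells, 15.5% of whose exonic length is overlapped on the opposite strand, from 3.48 ± 1.14 to 1.57 ± 0.726 CPM, with an adjusted p of 0.17 without p16- replicate 1. Of 2 epithelial genes, too few for the list test, 1 fell (2 adjusted over the list alone), the keratin gene Krt10, from 7.37 ± 0.834 to 4.35 ± 0.359 CPM, with an adjusted p of 0.0506 without p16- replicate 1.

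**Figure D2:**
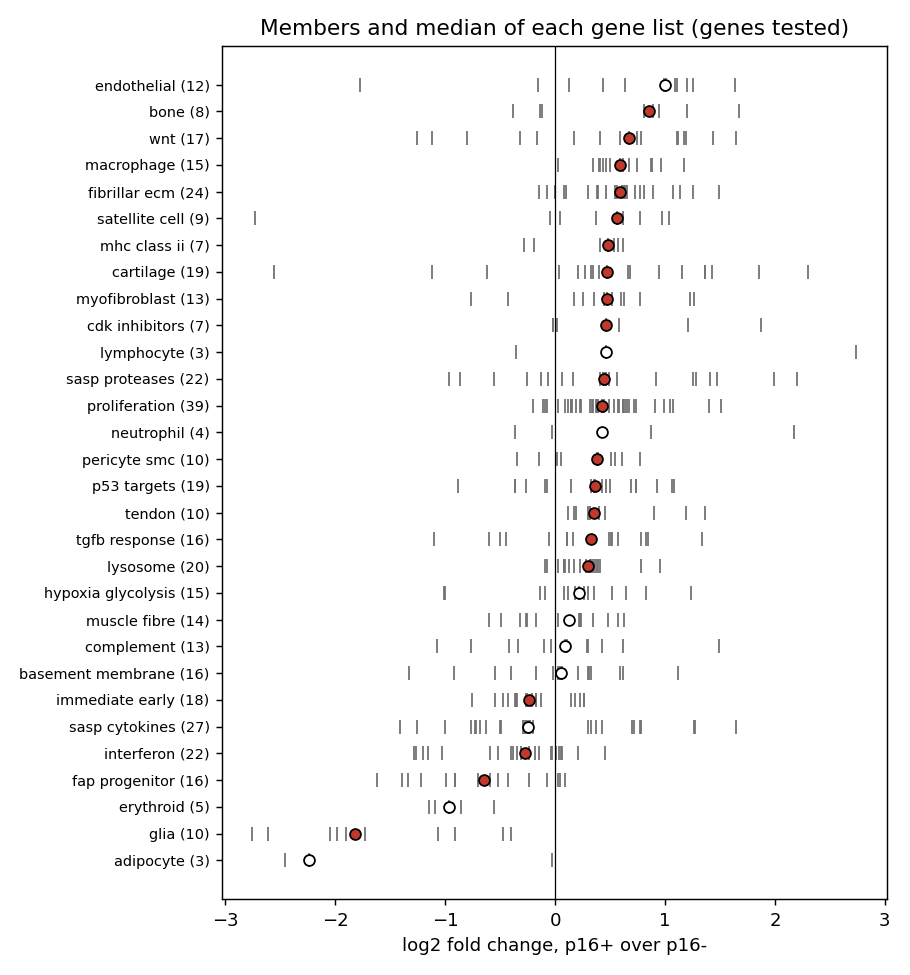
Log2 fold change of p16+ over p16- for the members of the 30 tested lists (grey ticks, 1 per gene) with the median of each list (circles, filled red where camera at its preset correlation passed the threshold); the number of genes tested stands in brackets. Medians ran from -1.82 for glia among the lists that passed, on the left, to 0.85 for bone on the right.

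In all, 20 of the 30 tested lists passed with camera at its preset correlation, 16 higher and 4 lower in p16+. With a correlation estimated from these libraries 0 passed (8 had an unadjusted p below 0.05). By fry 19 passed for a common direction and 25 for change in either direction. Unlike camera, fry tests whether members of a list changed at all, without comparison with the other genes. With 16.73% of the tested genes changed, many lists can pass it, so its counts cannot be set against those of camera.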

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

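The scalings with library sizes alone and without the 20 most abundant genes were chosen after seeing the data; the other alternatives were fixed before. The count of changed genes stayed within 1.5 times its value of 2660 under each alternative, from 1887 without p16- replicate 3 to 3114 with the replicate block. DESeq2 called 2833 genes and limma-voom 2672. Of the 2660 genes, 98.9% were also called by DESeq2 and 68.7% without p16- replicate 3. With library sizes alone 1059 genes were higher and 1882 lower. Cdkn2a stayed past the threshold in 17 alternatives, with log2 fold changes from 1.76 to 1.98. The number of lists past the threshold was 20; with camera at an estimated correlation it was 0 (8 at an unadjusted p below 0.05), and the cause was not tested. Of 156 other named genes, 137 kept their side of the threshold in each alternative run and 0 results reversed. Leaving out 1 library ended the calls of 15 genes and made those of 3. Same-numbered libraries deviated from their group means with correlations of 0.028, 0.082 and -0.005. Such low values over all genes cannot exclude pairs, and the block on replicate number called more genes than the main model. The labels do not say whether equal numbers mark the same animal, so the block was kept as an alternative and pairing stays open. With the number as a block, 2 named genes (Ccl7 and Dmp1) and 1 list (MHC class II) lost their call and 3 genes (Itgb1, Ptprc and Pdgfra) and 1 list (erythroid) gained it. At these depths the smallest simulated change, 1.5-fold, was recovered for 62% of genes, so a change of that size can be missed. The simulation changed 200 genes, while 2660 were called in the real data. The adjusted threshold was therefore stricter in the simulation, and its 62% is not the share recovered in the real comparison.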

Other observations

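The lists in this part were written after the main results had been seen. The tests on the second Schwann cell list, the heat shock list and the NF-kappaB list were written before those values were seen, and so was the count of splits. After a first run, the condition that such a list must also pass the list test was added, which made the NF-kappaB verdict more cautious. The tests on scaling, on single libraries, on leukocyte markers, on the lysosomal ratio and on the stromal share were chosen only after the result was seen.

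Of 21 genes of collagen processing, 18 rose and 1 fell in p16+ (camera adjusted p = 1.54e-09 over 9 such lists, adjusted p = 0.104 with an estimated correlation). The collagen chaperone gene Serpinh1 had 2433 CPM in p16+ and 1778 in p16-, and the prolyl hydroxylase gene P4ha3 143.9 and 68.5 CPM. The member that fell was Colgalt2, a collagen galactosyltransferase gene, with 23.3 and 52.9 CPM (edgeR adjusted p = 1.97e-06). Of 15 genes of BMP signalling, 1 rose and 9 fell (camera adjusted p = 0.000219, adjusted p = 0.104 with an estimated correlation). The ligand genes Bmp2, Bmp4, Bmp6 and Bmp7 fell, Bmp2 from 29.7 to 15.5 CPM and Bmp6 from 24.0 to 11.7 CPM. Fst, the follistatin gene, had 63.7 CPM in p16+ and 163 in p16-. These genes were named after their values were seen.

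Retinoid genes moved both ways without a call for the list (3 rose, 2 fell of 11; camera adjusted p = 0.379). Named after their values were seen, Aldh1a1 and Aldh1a3 fell by 0.91 and 1.54 on the log2 scale and Stra6 and Crabp2 rose by 1.40 and 1.70. Of 20 genes of oxidative phosphorylation 0 passed (camera adjusted p = 0.633), of 17 cholesterol synthesis genes 1 rose and 1 fell (camera adjusted p = 0.589), and of 8 perineurial genes 1 rose and 1 fell (camera adjusted p = 0.672).

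Glial genes were lower in p16+ libraries, a list call lost with an estimated correlation (adjusted p = 0.115). With library sizes alone the median log2 fold change of the glial list was -1.90. That scaling moved the median over all genes only from -0.008 to -0.083, so it could not have brought the glial median to 0. The glial fall thus did not come from the TMM factors, and other faults of scaling were not tested. Without p16- replicate 1, 8 of the 10 genes were still called lower, so that library alone did not make these 8 calls. Fewer Schwann cells among the sorted p16+ cells may account for the pattern, but a second Schwann cell list gave a median of -0.77, between the bounds set beforehand, with 8 genes lower and 2 higher (Ncam1 and Chl1, the latter with an adjusted p of 0.167 without p16- replicate 1; camera adjusted p = 0.0129, adjusted p = 0.4 with an estimated correlation). Lower expression within each glial cell and fewer glial cells cannot be told apart from bulk counts.

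Il6, Cxcl1, Cxcl2, Ccl2 and Ccl7, picked because they were seen to be lower in p16+ libraries, go against the direction usually associated with senescent cells; Ccl7 lost its call with the replicate block (adjusted p = 0.0901), and of the same list Ccl8, Cxcl12, Il33 and Ereg rose by 0.70, 0.71, 0.37 and 1.27 on the log2 scale, Il33 with an adjusted p of 0.144 without p16- replicate 3, 0.135 without p16+ replicate 2 and 0.152 without p16+ replicate 3. Fewer leukocytes would lower leukocyte markers, whose median was 0.59, which argues against that cause. Without p16- replicate 1, 5 of these 5 genes were still called lower, so that library alone did not make their calls. A weaker stress response to dissociation may contribute and stays open. Of 18 immediate-early genes 7 fell and 1 rose (camera adjusted p = 0.00924, and 0.538 with an estimated correlation). The heat shock list gave a median of -0.18, short of the bound set beforehand. Of its 12 genes 2 fell and 0 rose (camera adjusted p = 0.273). Lower NF-kappaB activity in p16+ cells is a hypothesis that also stays open, since the median of its target genes, -0.23, passed its bound by little, 4 members fell and 2 rose, and the list test gave an adjusted p of 0.379.

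In libraries sorted against CD45, 8 of 15 leukocyte markers and 11 of 20 lysosomal genes were higher in p16+, list calls lost with an estimated correlation (adjusted p = 0.236 and 0.178). With library sizes alone the macrophage median was 0.52, so the rise did not come from the TMM factors. That scaling moved the median over all genes only from -0.008 to -0.083, so it cannot decide on other faults of scaling. A lower share of stromal cells was taken to raise the markers of every other cell type alike. The glial median lay at -2.41 from the macrophage median (median absolute deviations 1.14 and 0.28). Glia can pass this gate, so their share need not rise where that of cells removed by the gate does. The difference therefore cannot decide whether the share of stromal cells was lower. Of other lists, the median of endothelium (1.00, list not passed at camera adjusted p = 0.143) was above 0. So was that of MHC class II (0.48), which is not a separate cell type. The medians of neutrophils (0.42, 4 genes) and lymphocytes (0.46, 3 genes) were above 0 too, but neither list passed (camera adjusted p = 0.417 for each). The satellite cell median (0.57) was also above 0, but a gate against CD45 and CD31 does not remove these cells, so it does not bear on carry-over. The medians of erythroid cells, adipocytes and epithelium (5, 3 and 2 genes) were below 0, with any 1 library left out too. More carry-over of some cells into the p16+ sort may account for the leukocyte markers and stays open. The lysosomal rise in summed CPM was 13.8 times that of the leukocyte list, whose most abundant member, Lyz2, was at 168 CPM; leukocyte RNA may supply part of it, which stays open because the ratio within leukocytes was not measured here, and a difference in lysosomal expression within p16+ stromal cells was not tested.

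The 6 libraries can be parted 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2660 genes, and 1 split, the real one, gave as many. The highest of the others gave 0 by edgeR, with 197 to 633 genes at an unadjusted p below 0.05 against 4473 in the real split. For the lists the real split gave 20, and 1 split, the real one, gave as many. The highest of the others gave 11, so camera at its preset correlation passed lists in splits with 0 changed genes. Each of the other splits has p16+ and p16- libraries on both sides in unequal numbers. Part of the real difference therefore remains in them, and their counts are not a rate of false calls.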
